A study of Homo sapiens with 27 samples.

How the data were processed

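RNA sequencing of poly(A)-selected RNA was carried out on 27 libraries from 3 human prostate cancer cell lines, LNCaP, 22Rv1 and LNCaP95. Per the labels' protocols, each line was treated for 6 days, without a change of medium, with the vehicle DMSO or with IPI-9119, an inhibitor of fatty acid synthase (FASN), at 100 nM or 500 nM. Each of the 9 groups held 3 replicates. The labels do not say whether replicates were separate cultures, so every p-value measures the spread between these libraries, which may be technical. Libraries were made with a directional kit and sequenced as paired ends, per the labels' protocols.

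Per the submitters' processing notes, the tools used before deposit included STAR 2.3.1z4, featureCounts and DESeq, and the genome build was hg19. The strand setting of the counting step is not given in the sources used here, so values of genes that overlap another gene, on either strand, are uncertain. Values of near-identical paralogs, here the UGT2B, AKR1C, PRSS and TUBA3 families and ribosomal protein genes with many pseudogenes, may share reads and are uncertain for the same reason. The deposited table gives for 20987 genes a normalised signal, the gene's count divided by a size factor of its library. All values of a library were whole multiples of its smallest value above 0, within a tolerance of 1e-06, in 27 of 27 libraries (100% of values), so whole reads could be recovered. The median-of-ratios factors computed from the recovered reads differed from those of the deposited values by a relative gap of at most 4e-15. A value of 1 read was worth 0.757 to 1.39 units, and libraries held 14757874 to 26578881 reads in genes. Of the genes, 1376 were at 0 in all libraries and 12478 were above 0 in all. Columns of no sample numbered 0. No coordinates were used, because the annotation at hand is of another build than hg19, and transcript lengths were taken from it by gene symbol alone.

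The design had assumed normalised values and a test on the log scale, and this was kept as the main analysis although whole reads were recovered. Deposited values were transformed as log2(value + 1) and tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, two-sided, and with Benjamini-Hochberg adjustment over the genes tested. Log2 fold changes are on this log2(value + 1) scale, which understates the change of genes with low values. Genes were kept where at least 3 of the fitted libraries had a value of 10 or more, and a gene was called changed at an adjusted p under 0.05. Comparisons within a line used 1 fit of its 9 libraries. Both doses of a line were set against the same 3 DMSO libraries, so likeness between the doses is not an independent repeat. The effect common to the lines used the 18 DMSO and 500 nM libraries with the line as a term. Differences of the effect between lines, and comparisons of the DMSO libraries of different lines, used 1 fit of all 27 libraries. That fit gives each gene 1 spread over all lines. Its errors and p-values therefore do not measure the spread of only the lines compared, which may be larger or smaller. For the common effect and the differences, genes had to pass the filter in each line. For the comparisons of DMSO libraries, the filter counted only the DMSO libraries, of all lines together. Errors after ± are standard errors of the log2 fold change, or standard deviations of normalised counts where a level is given, with n = 3 libraries per group.

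The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes were (a) a panel of 34 genes of lipid metabolism, androgen response, stress and proliferation; (b) in each 500 nM comparison with DMSO the 10 largest rises and the 10 largest falls among called genes whose higher group had a mean of 50 or more and whose groups did not overlap, in the 100 nM, common and untreated comparisons the 5 and 5 largest by the same rule, and in differences and dose comparisons the 5 and 5 largest called; and (c) up to 4 members with the smallest p of each list. Genes without an approved symbol were left out of part (b). Chance alone would separate 3 libraries from 3 without overlap in 10% of genes.

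Gene lists numbered 33, written from textbook knowledge. They were cholesterol synthesis, SREBP regulators and sterol uptake, fatty acid synthesis, elongation and desaturation, fatty acid uptake and activation, fatty acid oxidation, triglyceride synthesis and lipid droplets, phospholipid synthesis, LXR targets, androgen-induced and androgen-repressed genes, androgen synthesis, the ATF4 and amino acid response, ER chaperones, mitosis, DNA replication, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, p53 targets, glycolysis, hypoxia, the TCA cycle with nuclear OXPHOS genes, mitochondrially encoded genes, interferon response, NRF2 and pentose phosphate genes, heat shock, autophagy and lysosome, immediate early genes, and markers of luminal and basal epithelium, neuroendocrine cells, fibroblasts and leukocytes. Lists with 5 or more measured members were tested with camera (limma) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with a correlation estimated from the data, and with that setting 0 lists passed in any comparison. The smallest adjusted p it gave in a comparison of treated with DMSO libraries of 1 line was 0.117, and 0.0599 for the common effect. Counts of list members are given over all genes tested and, where they differ, adjusted over the list alone.

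Replicates were compared before they were averaged. The chi-square per degree of freedom of the recovered reads of 2 replicates lay between 5 and 63.7 over the 27 pairs, well above sampling noise, so each library was counted as 1 sample. The replicate numbers come from the labels, and whether they pair libraries across groups was checked by correlating the deviations from the group means. In LNCaP95 every pair of same-numbered libraries correlated at over 0.1 (0.13 to 0.30 for DMSO and 100 nM, 0.16 to 0.33 for DMSO and 500 nM, 0.29 to 0.47 for 100 and 500 nM), as did those of LNCaP for DMSO and 500 nM (0.13 to 0.32) and for 100 and 500 nM (0.26 to 0.39). Pairs of different numbers reached at most 0.05 in LNCaP95, -0.01 for LNCaP 100 and 500 nM, and 0.13 for LNCaP DMSO and 500 nM. The last value equalled the lowest of same-numbered pairs there. Between 22Rv1 DMSO and 100 nM, same-numbered pairs lay at -0.29 to 0.39 and pairs of different numbers at -0.53 to 0.52. Libraries thus shared differences there that the replicate numbers do not follow. These correlations run across genes, which are not independent replicates. The fit with the replicate number as a block is given where it moved a named gene, a list described in the text or a count across its threshold.

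The limma test of single genes was run on simulated reads with 200 genes changed by known folds. The 100 nM and dose comparisons and the list tests were not simulated. Genes were drawn independently of each other and without aberrant libraries. For the untreated comparisons all lines shared 1 set of means apart from the changed genes. The shares below hold for that setting, with fewer changed genes than limma called in the real data of these comparisons. Of genes changed 2-fold, limma recovered 77.6% in LNCaP, 81.8% in 22Rv1 and 83.7% in LNCaP95 over 12802, 13537 and 12775 genes. Of genes changed 1.5-fold it recovered 44%, 38% and 56%. For the common effect, 88% of genes changed 1.5-fold were recovered over 11593 genes. For the difference between 22Rv1 and LNCaP, 73.7% of genes changed 2-fold were recovered over 11727 genes, and 21 of 154 calls were false, more than the 5% aimed at. For the difference between LNCaP95 and LNCaP 14 of 152 calls were false, and for untreated LNCaP95 11 of 154, both above 5% as well. False calls in the simulated line comparisons were 7 of 155 in LNCaP, 13 of 162 in 22Rv1 and 12 of 172 in LNCaP95, of which the latter 2 also lay above 5%.

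Alternatives were a pseudocount of 8, no filter, a filter at 50, quantile normalisation, rescaling each library to the same total, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, array weights, the replicate block, a fit of all 27 libraries, a fit of only the 6 libraries compared, and leaving out each library in turn. Alternatives chosen after seeing the data were LNCaP replicates 2 and 3 only, fry (limma) for the lists, equal totals for the lists, and lists in 22Rv1 without DMSO replicate 3. Other splits of the same libraries were fitted in full for 10 splits of 3 against 3, and 100 splits were drawn elsewhere.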

Results

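Gene expression was measured by RNA sequencing in 27 libraries from 3 human prostate cancer cell lines. LNCaP, derived from a lymph node metastasis, is labelled androgen sensitive. 22Rv1, derived from a relapsed xenograft, and LNCaP95, a derivative of LNCaP kept without androgen, are labelled castration resistant. Cells of each line received DMSO, 100 nM or 500 nM IPI-9119 for 6 days. IPI-9119 inhibits fatty acid synthase, the enzyme encoded by FASN that makes palmitate from acetyl-CoA and malonyl-CoA. Each group held 3 libraries. Reads in genes numbered 14757874 to 25731706 per library in LNCaP, 15642743 to 26578881 in 22Rv1 and 15073809 to 23565696 in LNCaP95. Values are the deposited normalised read counts, with log2 fold changes on the log2(value + 1) scale.

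Some libraries stood apart from others of their group. In LNCaP, DMSO replicate 1 had a mean log2 level of 10.13 over the mitosis list, against 8.66 and 8.44 in replicates 2 and 3, and FASN in the 100 nM libraries was 227500 in replicate 1 against 51990 and 45540 in the other 2. In 22Rv1, DMSO replicate 3 had 18444 genes above 0, against 15585 to 15962 in the other 8 libraries of the line. The treated replicate 2 libraries of LNCaP95 had 7.56% (100 nM) and 6.92% (500 nM) of their counts in mitochondrially encoded genes. The ribosomal protein list took 6.42% of counts in 22Rv1 100 nM replicate 2.

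The comparison of 500 nM IPI-9119 with DMSO in LNCaP asked which genes respond to FASN inhibition in the androgen-sensitive line (n = 3 libraries per group). Genes of sterol synthesis rose, along with several single genes of fatty acid metabolism. FASN itself rose by 2.14 ± 0.519 on the log2 scale (adjusted p = 0.0145), and SCD, the desaturase that makes monounsaturated fatty acids, by 2.85 ± 0.505 (adjusted p = 0.00285). SREBF1, which encodes a transcription factor of lipogenic genes, rose by 1.20 ± 0.212, and HMGCS1, an early enzyme of cholesterol synthesis, by 2.17 ± 0.403. INSIG1, a sterol-regulated brake on that programme, rose by 2.87 ± 0.576. Of 20 measured genes of cholesterol synthesis, 17 rose and 0 fell (median log2 fold change 1.20, camera adjusted p = 7.07e-09, adjusted p = 0.522 with an estimated correlation), among them FDFT1 (2.06 ± 0.349), IDI1 (1.54 ± 0.239) and SQLE (1.10 ± 0.188). Of 12 SREBP regulators and sterol uptake genes, 9 rose and 0 fell, and 11 rose adjusted over the list alone (median 1.04, adjusted p = 4.24e-07, adjusted p = 0.522 with an estimated correlation), with the cholesterol transporter NPC1 at 2.16 ± 0.185. Of 15 genes of fatty acid elongation and desaturation, 8 rose and 1 fell (median 0.32, adjusted p = 0.00823, adjusted p = 0.522 with an estimated correlation), with FADS2 at 1.86 ± 0.268 and ELOVL6 at 2.05 ± 0.325. FASN lost its call without DMSO replicate 2 (2.00, adjusted p = 0.0531), without DMSO replicate 3 (1.98, adjusted p = 0.0585) or without 500 nM replicate 1 (1.86, adjusted p = 0.0596). The mean log2 level of the cholesterol list was 12.05 in 500 nM replicate 1 and 11.46 and 11.47 in replicates 2 and 3, against 10.73, 10.42 and 10.43 with DMSO.

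Genes of fatty acid oxidation went the other way in part. CPT1A, the gatekeeper of fatty acid entry into mitochondria, fell by 1.57 ± 0.249 on the log2 scale (adjusted p = 0.00151), as did the carnitine carrier SLC25A20 (-0.98 ± 0.176) and the dehydrogenase ACADVL (-0.77 ± 0.104). The list as a whole did not pass (1 up and 5 down of 20, 1 and 6 adjusted over the list alone, adjusted p = 0.0614). The fatty acid synthesis list did not pass either (2 up of 10, adjusted p = 0.0968). With the replicate number as a block both passed, oxidation at 0.0471 (adjusted p = 0.476 with an estimated correlation) and synthesis at 0.0122 (adjusted p = 0.454 with an estimated correlation). With replicates 2 and 3 only they passed as well (0.0151 and 0.00803). Of 20 genes of phospholipid synthesis, 6 rose and 0 fell, with 7 up and 1 down adjusted over the list alone (median 0.25, adjusted p = 0.00446, adjusted p = 0.522 with an estimated correlation), among them LPCAT1 at 1.05 ± 0.116. Some prostate genes known to be induced by androgen were lower. KLK3, which encodes prostate-specific antigen, went from 12450 ± 648 to 3290 ± 702 normalised counts (SD, n = 3), a log2 fold change of -1.94 ± 0.198 (adjusted p = 9.72e-05). KLK2 (-1.62 ± 0.247) and TMPRSS2 (-1.24 ± 0.18) also fell. Over 37 androgen-induced genes, 2 rose and 9 fell, and the list did not pass (median -0.13, adjusted p = 0.0847). Of 9 genes of androgen synthesis, 5 rose and 0 fell, with 5 and 1 adjusted over the list alone (median 0.82, adjusted p = 0.014, adjusted p = 0.522 with an estimated correlation), among them SRD5A1, a steroid reductase, at 0.82 ± 0.152 and AKR1C1 at 2.60 ± 0.363, a gene with close paralogs. Under fry, a test of each list by itself, the elongation and desaturation list (adjusted p = 0.0556) and the androgen synthesis list (adjusted p = 0.0609) did not pass. Nor did fatty acid oxidation (0.0556) or fatty acid synthesis (0.327) under fry.

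The amino acid and integrated stress response genes fell in LNCaP. ATF4, the transcription factor of that response, fell by 1.13 ± 0.134 on the log2 scale (adjusted p = 0.000243), ASNS, asparagine synthetase, by 1.51 ± 0.164, and TRIB3 by 1.23 ± 0.164. PCK2, a mitochondrial gluconeogenic enzyme, was at -1.83 ± 0.106 (adjusted p = 4.71e-06). Of 33 genes of the ATF4 list, 2 rose and 28 fell, 29 adjusted over the list alone (median -1.05, adjusted p = 2.47e-20, adjusted p = 0.49 with an estimated correlation). Some proliferation genes were higher than with DMSO. CDK1, the mitotic kinase, rose 2.82-fold (adjusted p = 0.0048) and CCNE2, a cyclin of S phase entry, by 1.66 ± 0.202 on the log2 scale. Of 31 DNA replication genes, 14 rose and 0 fell, 17 adjusted over the list alone (median 0.64, adjusted p = 1.28e-07, adjusted p = 0.522 with an estimated correlation). Of 26 mitosis genes, 4 rose and 0 fell, 1 adjusted over the list alone (median 0.88, adjusted p = 1.13e-05, adjusted p = 0.552 with an estimated correlation). Under fry, mitosis (adjusted p = 0.206) and DNA replication (adjusted p = 0.0992) did not pass. The mean log2 level of the mitosis list in DMSO replicate 1 (10.13) lay above those of the 500 nM libraries (9.81, 10.06 and 10.02), while DMSO replicates 2 and 3 (8.66 and 8.44) lay below them. With LNCaP replicates 2 and 3 only, the medians were 1.46 for mitosis and 0.87 for DNA replication. Cytosolic ribosomal protein genes were lower in 21 of 25 cases, 25 adjusted over the list alone (median -0.53, adjusted p = 2.73e-11, adjusted p = 0.522 with an estimated correlation), RPS19 for example at -0.64 ± 0.119. Of 18 interferon response genes, 9 rose and 0 fell, 11 adjusted over the list alone (median 0.54, adjusted p = 1.13e-05, adjusted p = 0.49 with an estimated correlation), with IFIT1 at 2.32 ± 0.384 and IFI44 at 1.57 ± 0.179.

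Among the largest rises in LNCaP at 500 nM were AGR2, a secreted disulfide isomerase (5.58 ± 0.271, 47.7-fold, adjusted p = 3.01e-06), DIO3, a thyroid hormone deiodinase (5.32 ± 0.606), NOS3, endothelial nitric oxide synthase (4.89 ± 0.486), the matrix metalloproteinase MMP10 (4.63 ± 0.343) and the laminin chain LAMB3 (4.03 ± 0.206). Among the largest falls were NDUFA4L2, a hypoxia-regulated mitochondrial protein (-2.81 ± 0.217), TSC22D3, a steroid-induced leucine zipper protein (-2.03 ± 0.134), and the phosphatase DUSP4 (-1.94 ± 0.14). In all, limma called 2671 of 12837 genes, 1409 higher and 1262 lower, and 702 of them changed at least 2-fold. The share of calls that were higher was 52.8%, and 68.9% when libraries were scaled to the same total. The count depended on single libraries: it was 1572 without DMSO replicate 2, 1475 without DMSO replicate 3, and 1556, 1603 and 1548 without 500 nM replicates 1, 2 and 3.

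The comparison of 100 nM with DMSO in LNCaP asked whether the lower dose already alters expression (n = 3 libraries per group). ATF4 fell by 1.60 ± 0.134 on the log2 scale (adjusted p = 4.08e-05), ASNS by 1.85 ± 0.164, TRIB3 by 1.93 ± 0.164, and DDIT3, a stress-induced transcription factor, by 1.65 ± 0.154. The ATF4 list had 0 genes up and 31 down of 33 (median -1.27, adjusted p = 7.74e-29, adjusted p = 0.246 with an estimated correlation). CDK1 rose by 1.93 ± 0.292 and CCNE2 by 1.74 ± 0.202. Mitosis genes had 22 of 26 up, 26 adjusted over the list alone (median 1.42, adjusted p = 1.93e-09, adjusted p = 0.621 with an estimated correlation, 0.0712 under fry). DNA replication genes had 27 of 31 up, 29 adjusted over the list alone (median 1.03, adjusted p = 1.44e-14, adjusted p = 0.619 with an estimated correlation). KLK3 fell by 1.71 ± 0.198, KLK2 by 1.40 ± 0.247 and TMPRSS2 by 1.03 ± 0.18. Cholesterol genes had 11 of 20 up, 12 adjusted over the list alone (median 0.87, adjusted p = 2.98e-05, adjusted p = 0.621 with an estimated correlation, 0.084 under fry), with the sterol isomerase EBP at 1.37 ± 0.216. FASN was at 1.18 ± 0.519 (adjusted p = 0.115), and at 0.44 (adjusted p = 0.347) without 100 nM replicate 1. With LNCaP replicates 2 and 3 only, FASN was at 0.75 (adjusted p = 0.00101), and the list medians were 0.56 for cholesterol synthesis, 2.23 for mitosis and 1.49 for DNA replication. SCD rose by 1.77 ± 0.505 (adjusted p = 0.0256), and lost the call without DMSO replicate 2 (1.53, adjusted p = 0.0946), DMSO replicate 3 (1.47, adjusted p = 0.102) or 100 nM replicate 1 (1.16, adjusted p = 0.0676). AGR2 (4.71 ± 0.271) and NOS3 (4.47 ± 0.486) were among the largest rises, and NDUFA4L2 (-3.02 ± 0.217) and DMGDH, a choline catabolism enzyme (-3.05 ± 0.422), among the largest falls.

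Limma called 3250 of 12837 genes at 100 nM in LNCaP, 1765 higher and 1485 lower, with a share higher of 54.3%, or 65.7% at equal totals. Without DMSO replicate 2 the count was 1753, without DMSO replicate 3 it was 1736, and without 100 nM replicate 2 it was 1894. Between 500 nM and 100 nM, which asked whether the response grows with dose, 1 gene passed, DDIT3, higher at 500 nM by 1.38 ± 0.154 (adjusted p = 0.024), with 1463 genes at an unadjusted p under 0.05 against 642 expected by chance. edgeR called 1 gene and DESeq2 93. Limma called 0 with the replicate number as a block, 49 with all 27 libraries in 1 fit, 123 with array weights, 0 with only the 6 libraries compared and 755 with replicates 2 and 3 only. Leaving out a library gave 67 genes without 100 nM replicate 1, 5 without 500 nM replicate 1, and 0 without 100 nM replicate 2 or 3 or 500 nM replicate 2 or 3. The ATF4 list was higher at 500 nM than at 100 nM (1 up of 33, 13 adjusted over the list alone, median 0.33, adjusted p = 2.45e-15, adjusted p = 0.403 with an estimated correlation, 0.153 under fry). Cholesterol synthesis genes were higher as a list (0 called of 20, median 0.42, adjusted p = 0.000555, adjusted p = 0.782 with an estimated correlation, 0.642 under fry). Fatty acid synthesis genes did not pass (adjusted p = 0.0818, 0.809 under fry), and did with the block (0.00964, adjusted p = 0.54 with an estimated correlation). DNA replication genes were lower (0 called of 31, median -0.41, adjusted p = 2.04e-11, adjusted p = 0.48 with an estimated correlation, 0.411 under fry).

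**Figure D1:**
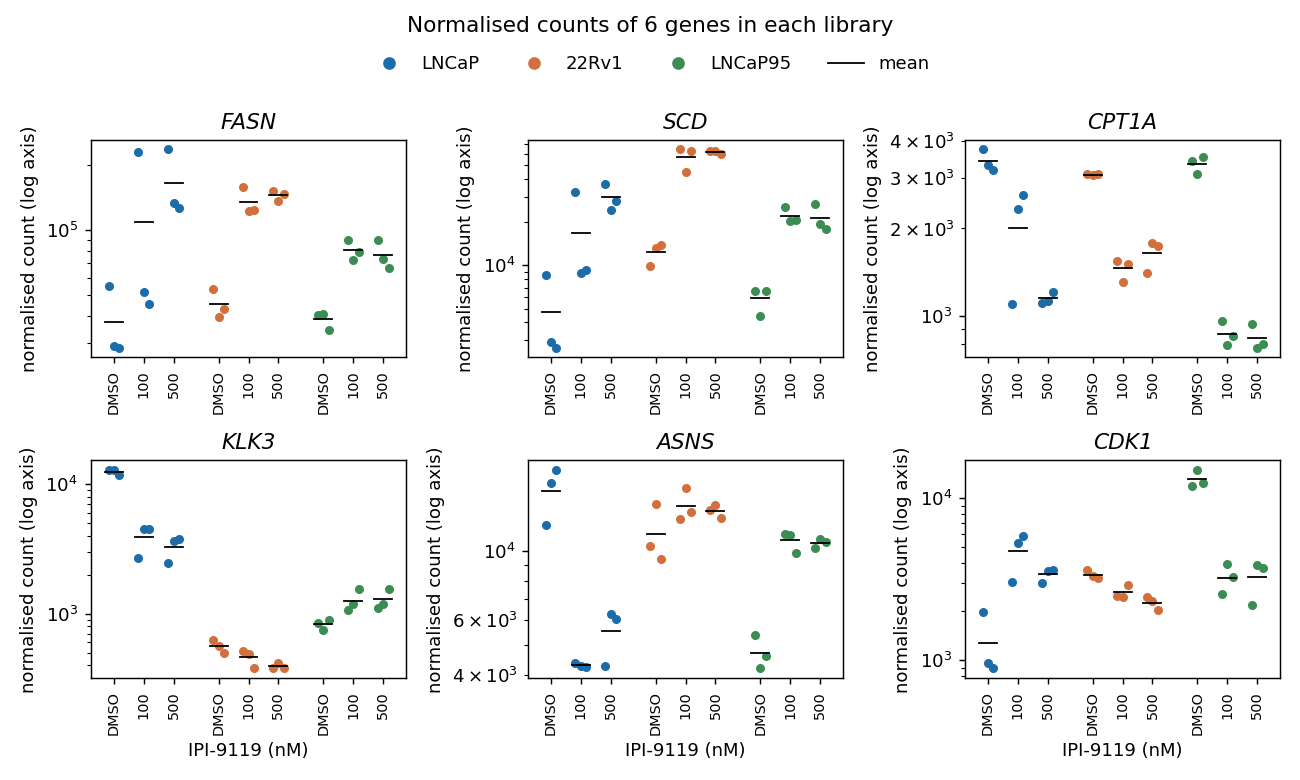
Normalised read counts (log axis) of FASN, SCD, CPT1A, KLK3, ASNS and CDK1 in each of the 27 libraries, by cell line and IPI-9119 concentration, with points for libraries and black bars for the mean of 3. KLK3 fell from a mean of 12450 with DMSO to 3290 at 500 nM in LNCaP, while ASNS went from 15690 to 5514 in LNCaP and from 4711 to 10630 in LNCaP95.

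In 22Rv1, the comparison of 500 nM with DMSO put the same question to a castration-resistant line (n = 3 libraries per group). The lipogenic genes rose here too. FASN went from 45480 ± 7110 to 144600 ± 7629 normalised counts (SD, n = 3), a log2 fold change of 1.68 ± 0.138 (adjusted p = 5.33e-05). SCD rose by 2.33 ± 0.156, SREBF1 by 1.36 ± 0.107, and ACACA, the carboxylase that supplies malonyl-CoA, by 1.09 ± 0.141. Cholesterol synthesis genes had 13 of 20 up and 0 down, 19 up adjusted over the list alone (median 0.68, adjusted p = 1.03e-17, adjusted p = 0.118 with an estimated correlation), with LSS at 1.01 ± 0.094. Fatty acid synthesis genes had 6 of 9 up and 0 down, 7 up and 2 down adjusted over the list alone (median 0.59, adjusted p = 2.54e-06, adjusted p = 0.118 with an estimated correlation). SREBP regulators and sterol uptake genes had 6 of 13 up, 7 adjusted over the list alone (median 0.37, adjusted p = 1.63e-05, adjusted p = 0.169 with an estimated correlation). LXR targets had 3 up and 1 down of 7 (median 0.48, adjusted p = 0.00312, adjusted p = 0.118 with an estimated correlation), led by the sterol exporter ABCG1, up by 2.59 ± 0.144 (6.04-fold), and MYLIP, a ubiquitin ligase, up by 1.03 ± 0.144. Camera did not call the LXR list at 500 nM in LNCaP or LNCaP95. Under fry it was higher in LNCaP (adjusted p = 0.019), 22Rv1 (0.000398) and LNCaP95 (6.97e-06). The cholesterol exporter ABCA1 was called higher at 500 nM in LNCaP and 22Rv1 but lower in LNCaP95. Its effect in LNCaP95 differed by -1.86 from that in LNCaP and by -2.47 from that in 22Rv1. CPT1A fell by 0.91 ± 0.108 (adjusted p = 0.000551). Fatty acid oxidation genes had 1 up and 4 down of 21, 2 and 6 adjusted over the list alone (median -0.15, adjusted p = 0.00698, adjusted p = 0.287 with an estimated correlation).

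Of the stress genes named for LNCaP, ATF4 and ASNS did not pass in 22Rv1. ATF4 was at -0.11 ± 0.134 (adjusted p = 0.673) and ASNS at 0.27 ± 0.143 (adjusted p = 0.286), and the ATF4 list had 2 up and 2 down of 33, 2 and 3 adjusted over the list alone (adjusted p = 0.186). KLK2 was at -0.37 ± 0.118 (adjusted p = 0.0823) and TMPRSS2 at -0.19 ± 0.169 (adjusted p = 0.564). KLK3 was at -0.51 ± 0.137 (adjusted p = 0.0431), a call lost without DMSO replicate 1 (0.111), 2 (0.126) or 3 (0.0519), without 500 nM replicate 1 (0.134), 2 (0.0967) or 3 (0.131), with no filter (0.0576), and also under quantile normalisation and with all 27 libraries in 1 fit. Androgen-induced genes went both ways, with 3 up and 5 down of 35, 4 and 7 adjusted over the list alone (median 0.02, mean -0.01, adjusted p = 0.987, and 1.99e-07 under fry for change in either direction). SLC45A3, a prostate transporter, fell by 1.05 ± 0.136. Proliferation genes were lower by small amounts. Mitosis genes had 0 up and 8 down of 26, 13 adjusted over the list alone (median -0.28, adjusted p = 5.41e-09, adjusted p = 0.118 with an estimated correlation). DNA replication genes had 0 up and 5 down of 31, 1 and 14 adjusted over the list alone (median -0.27, adjusted p = 1.55e-08, adjusted p = 0.12 with an estimated correlation), with RFC4 at -0.70 ± 0.107. CDKN1A, the inhibitor of cyclin-dependent kinases also called p21, rose 2.0-fold (adjusted p = 9.27e-05). GDF15, a stress-induced cytokine, rose by 1.85 ± 0.206 on the log2 scale. Immediate early genes had 0 up and 5 down of 12, 6 adjusted over the list alone (median -0.51, adjusted p = 0.000121, adjusted p = 0.287 with an estimated correlation), JUN for example at -0.89 ± 0.121.

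The largest rises in 22Rv1 at 500 nM included GPNMB, a lysosome-associated membrane protein (2.73 ± 0.121, adjusted p = 1.75e-07), LAMP3 (2.48 ± 0.307) and IGFBP3 (2.41 ± 0.201). The largest falls included genes best known from liver: ALB, albumin (-2.29 ± 0.098), CYP2C8 (-2.83 ± 0.348), APOH (-1.77 ± 0.213) and the bile acid receptor NR1H4 (-2.12 ± 0.256). No list of liver genes was fixed in advance, so this group was tested only gene by gene. Mitochondrially encoded genes had 6 of 13 up, 12 adjusted over the list alone (median 0.49, adjusted p = 5.41e-09, adjusted p = 0.169 with an estimated correlation). NRF2 and pentose phosphate genes had 7 of 15 up, 8 adjusted over the list alone (median 0.41, adjusted p = 4.29e-06, adjusted p = 0.118 with an estimated correlation). Autophagy and lysosome genes had 6 of 18 up, 10 up and 1 down adjusted over the list alone (median 0.34, adjusted p = 1.27e-05, adjusted p = 0.281 with an estimated correlation). NEU1, a lysosomal sialidase, rose by 1.02 ± 0.101 and SQSTM1, an autophagy receptor, by 0.94 ± 0.113.

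Limma called 946 of 13563 genes at 500 nM in 22Rv1, 471 higher and 475 lower, 212 of them at least 2-fold. The share higher was 49.8%, and 26.6% at equal totals. Without DMSO replicates 2 and 3 in turn the count was 447 and 494, and without 500 nM replicates 1, 2 and 3 it was 398, 384 and 453. At 100 nM, 889 genes were called, 433 higher and 456 lower (48.7% higher, 26.9% at equal totals), a count that was 363 without DMSO replicate 2, 402 without DMSO replicate 3 and 261 without 100 nM replicate 1. Another split of the same libraries, which set DMSO replicate 1 with 100 nM replicates 1 and 2, gave 1223 genes. At 100 nM FASN rose by 1.56 ± 0.138 on the log2 scale (adjusted p = 7.27e-05), SCD by 2.21 ± 0.156, ABCG1 by 2.50 ± 0.144 and GPNMB by 2.75 ± 0.121, while CPT1A fell by 1.08 ± 0.108 and ALB by 2.19 ± 0.098. Cholesterol synthesis genes had 14 of 20 up, 19 adjusted over the list alone (median 0.69, adjusted p = 1.99e-19, adjusted p = 0.117 with an estimated correlation). Mitosis genes had 5 of 26 down, 14 adjusted over the list alone (median -0.29, adjusted p = 2.84e-08, adjusted p = 0.117 with an estimated correlation). Between 500 nM and 100 nM limma called 0 genes, with 152 at an unadjusted p under 0.05 against 678 expected by chance, and edgeR and DESeq2 called 0 each.

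The comparison of 500 nM with DMSO in LNCaP95 asked the same of the other castration-resistant line (n = 3 libraries per group). Genes of sterol synthesis rose, along with FASN and SCD. FASN went from 38710 ± 3616 to 76740 ± 12070 normalised counts (SD, n = 3), a log2 fold change of 0.98 ± 0.14 (adjusted p = 7.1e-05). SCD rose by 1.86 ± 0.17, SREBF1 by 1.27 ± 0.069, INSIG1 by 1.54 ± 0.096 and ABCG1 by 2.75 ± 0.08 (6.74-fold). ABCA1, another sterol exporter, was called lower. Cholesterol synthesis genes had 17 up and 2 down of 20 (median 0.66, adjusted p = 5.48e-06, adjusted p = 0.287 with an estimated correlation), with MSMO1 at 1.32 ± 0.089 and IDI1 at 0.83 ± 0.073. SREBP regulators and sterol uptake genes had 9 up and 1 down of 11 (median 0.89, adjusted p = 0.000228, adjusted p = 0.287 with an estimated correlation). CPT1A fell by 2.00 ± 0.093 (adjusted p = 5.8e-08), from 3349 to 836 normalised counts. Fatty acid oxidation genes had 4 up and 11 down of 20 (median -0.23, adjusted p = 0.0336, adjusted p = 0.287 with an estimated correlation, 0.0591 under quantile normalisation), ACAA2 for example at -1.10 ± 0.129. The fatty acid synthesis list (5 up and 1 down of 9, adjusted p = 0.0978) and the elongation and desaturation list (9 up and 2 down of 15, adjusted p = 0.0825) did not pass with camera. Under fry, which tests each list by itself, both did (0.000211 and 0.000768), and with the replicate block camera called the latter (0.0496, adjusted p = 0.293 with an estimated correlation).

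All 34 measured genes of the ATF4 and amino acid response rose in LNCaP95 (median 1.24, adjusted p = 1.86e-17, adjusted p = 0.287 with an estimated correlation). ATF4 rose 2.0-fold (adjusted p = 1.57e-06). DDIT3 rose by 1.92 ± 0.157 on the log2 scale, TRIB3 by 1.66 ± 0.114, ASNS by 1.18 ± 0.094 and SLC3A2, a subunit of amino acid transporters, by 1.78 ± 0.109. ER chaperones and XBP1/ATF6 targets had 17 up and 1 down of 25 (median 0.46, adjusted p = 6.67e-05, adjusted p = 0.288 with an estimated correlation), with DNAJB9 at 2.12 ± 0.115 and HERPUD1 at 1.40 ± 0.089. Proliferation genes fell throughout their lists. All 26 mitosis genes (median -1.37, adjusted p = 3.33e-15, adjusted p = 0.287 with an estimated correlation) and all 31 DNA replication genes (median -1.18, adjusted p = 1.31e-18, adjusted p = 0.287 with an estimated correlation) were lower, CDK1 by 2.04 on the log2 scale (13080 ± 1594 to 3270 ± 933, SD), MKI67 at -1.71 ± 0.259, MCM4 at -1.42 ± 0.104 and E2F1 at -1.15 ± 0.092. CCND1, cyclin D, fell by 0.94 ± 0.107, and CDKN1A rose by 1.21 ± 0.09. Ribosome biogenesis and MYC targets had 1 up and 20 down of 23, 22 down adjusted over the list alone (median -0.62, adjusted p = 1.16e-08, adjusted p = 0.287 with an estimated correlation), NOP56 for example at -0.85 ± 0.066.

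Genes of central metabolism fell in LNCaP95. Glycolysis genes had 2 up and 14 down of 20 (median -0.44, adjusted p = 0.00116, adjusted p = 0.287 with an estimated correlation), LDHA, lactate dehydrogenase, at -1.21 ± 0.122. TCA cycle and nuclear OXPHOS genes had 0 up and 18 down of 26 (median -0.38, adjusted p = 6.11e-06, adjusted p = 0.287 with an estimated correlation). Heat shock genes had 0 up and 9 down of 12, 10 down adjusted over the list alone (median -0.34, adjusted p = 0.00186, adjusted p = 0.287 with an estimated correlation). Autophagy and lysosome genes had 15 up of 18, 16 adjusted over the list alone (median 0.51, adjusted p = 1.31e-06, adjusted p = 0.287 with an estimated correlation), with WIPI1 at 1.44 ± 0.126 and MAP1LC3B at 1.33 ± 0.095. NRF2 and pentose phosphate genes had 9 up and 1 down of 15 (median 0.30, adjusted p = 0.00571, adjusted p = 0.335 with an estimated correlation), with the iron storage genes FTL (1.20 ± 0.067) and FTH1 (1.63 ± 0.183) and the cystine transporter SLC7A11 (1.98 ± 0.138). KLK3 rose by 0.61 ± 0.142 (adjusted p = 0.00266), from 835 ± 76.2 to 1290 ± 237 normalised counts (SD, n = 3). FKBP5, a chaperone gene induced by steroid receptors, fell by 1.04 ± 0.087 on the log2 scale. Androgen-induced genes as a list had 12 up and 8 down of 35 (median 0.06, adjusted p = 0.913), with ACPP, prostatic acid phosphatase, up 2.82-fold.

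Among the largest rises in LNCaP95 were LCN2, lipocalin (5.48 ± 0.483, 44.6-fold), KLHDC7B (4.46 ± 0.257) and the collagen receptor DDR2 (3.92 ± 0.44). Among the largest falls were CA9, a carbonic anhydrase induced by hypoxia (-3.33 ± 0.223), the immediate early gene EGR1 (-3.11 ± 0.73) and CORO1A (-2.72 ± 0.339). Limma called 6715 of 12844 genes at 500 nM, 3623 higher and 3092 lower, 1232 of them at least 2-fold, and 6713 at 100 nM, 3616 higher and 3097 lower. The 100 nM values were close to those at 500 nM, with the same DMSO libraries in both comparisons. FASN rose by 1.05 ± 0.14, SCD by 1.93 ± 0.17, ATF4 by 0.91 ± 0.087, ASNS by 1.21 ± 0.094 and KLK3 by 0.58 ± 0.142, while CPT1A fell by 1.96 ± 0.093 and CDK1 by 2.03 ± 0.193. Lists at 100 nM included the ATF4 response (34 of 34 up, median 1.21, adjusted p = 2.26e-17, adjusted p = 0.271 with an estimated correlation), mitosis (26 of 26 down, median -1.38, adjusted p = 4.79e-15, adjusted p = 0.271 with an estimated correlation) and cholesterol synthesis (17 up and 2 down of 20, median 0.62, adjusted p = 9.17e-06, adjusted p = 0.271 with an estimated correlation). Between 500 nM and 100 nM limma called 0 genes, with 95 at an unadjusted p under 0.05 against 642 expected by chance. With the replicate block limma also called 0, edgeR and DESeq2 called 0 each, and the smallest adjusted p of a list was 0.0701.

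**Figure D2:**
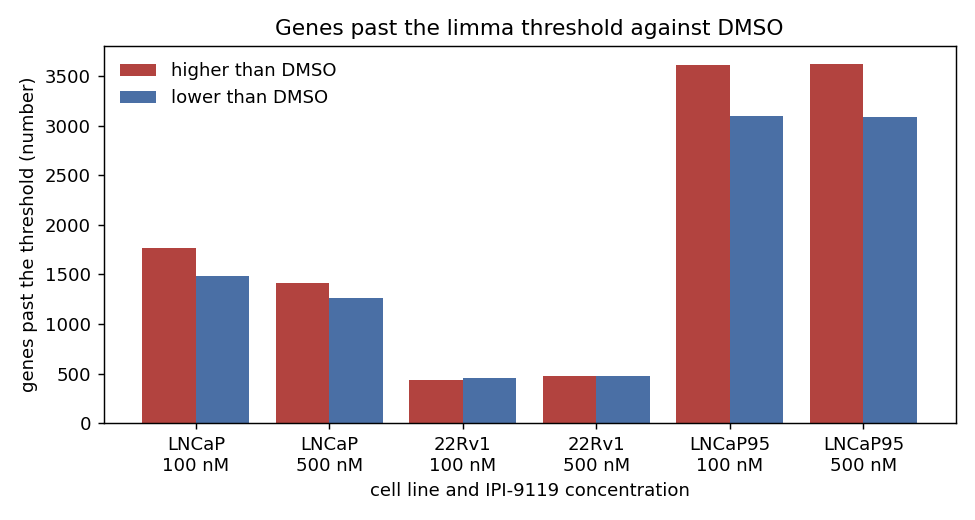
Number of genes past the limma threshold against DMSO (vertical axis, from 0), higher in red and lower in blue, for each cell line and IPI-9119 concentration. The counts ran from 433 higher and 456 lower in 22Rv1 at 100 nM to 3623 higher and 3092 lower in LNCaP95 at 500 nM.

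The effect common to the 3 lines at 500 nM, estimated over 18 libraries with the line as a term, asked which changes the lines had on average (n = 9 libraries per arm). GPNMB rose by 3.17 ± 0.16 on the log2 scale (adjusted p = 2.94e-10), ABCG1 by 2.37 ± 0.125, SCD by 2.35 ± 0.201, FASN by 1.60 ± 0.178 (3.03-fold), HMGCS1 by 1.49 ± 0.163 and SREBF1 by 1.28 ± 0.061. CPT1A was 2.82-fold lower (adjusted p = 1.83e-07), and SLC25A20 fell by 0.72 ± 0.084 on the log2 scale. CDKN1A rose by 0.98 ± 0.088, and MYC, a transcription factor of growth, fell by 0.46 ± 0.075. Cholesterol synthesis genes had 17 up of 20, 18 adjusted over the list alone (median 0.86, adjusted p = 4.61e-17, adjusted p = 0.0599 with an estimated correlation). SREBP regulators and sterol uptake genes had 9 of 11 up (median 0.91, adjusted p = 6.59e-09, adjusted p = 0.0599 with an estimated correlation). Fatty acid synthesis genes had 7 up and 1 down of 9 (median 0.59, adjusted p = 0.000464, adjusted p = 0.166 with an estimated correlation). Elongation and desaturation genes had 8 of 13 up, 9 adjusted over the list alone (median 0.33, adjusted p = 1.77e-05, adjusted p = 0.0599 with an estimated correlation). Fatty acid oxidation genes had 1 up and 8 down of 20 (median -0.11, adjusted p = 0.000464, adjusted p = 0.0599 with an estimated correlation). Autophagy and lysosome genes had 13 of 18 up (median 0.36, adjusted p = 4.28e-09, adjusted p = 0.0599 with an estimated correlation), with SQSTM1 at 1.17 ± 0.089 and NEU1 at 1.09 ± 0.076. ER chaperones had 11 of 25 up, 13 adjusted over the list alone (median 0.24, adjusted p = 6.05e-06, adjusted p = 0.196 with an estimated correlation). Neither ATF4 (-0.08 ± 0.215, adjusted p = 0.822) nor CDK1 (-0.37 ± 0.361, adjusted p = 0.486) passed.

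Limma called 2658 of 11612 genes for the common effect, 1513 higher and 1145 lower, 126 of them at least 2-fold. The lines had separate DMSO libraries, so no shared control ties their calls at 500 nM. Expected numbers below are those of independent lists of the same sizes. Genes with a small spread may be called more readily in every line, so an excess over these numbers alone does not show a shared response. Of 11761 genes tested in all lines, 101 were called higher in each line (11.7 expected) and 19 lower in each (9.12 expected). LNCaP and 22Rv1 shared 142 genes called higher (41.9 expected), and 22Rv1 and LNCaP95 shared 260 (113 expected). In opposite directions, 42 were higher in LNCaP and lower in 22Rv1 (37.8 expected), and 27 the reverse (40.7 expected). Between 22Rv1 and LNCaP95, 35 were higher in 22Rv1 and lower in LNCaP95 (101 expected), and 47 the reverse (102 expected). LNCaP and LNCaP95 shared 477 genes called higher (340 expected) and 198 called lower (294 expected). Of genes called in both, 451 were lower in LNCaP and higher in LNCaP95 (330 expected), and 280 were higher in LNCaP and lower in LNCaP95 (303 expected). For this pair, genes higher in LNCaP95 exceeded the expected number whether they were higher or lower in LNCaP. Across genes, log2 fold changes correlated at 0.19 between LNCaP and 22Rv1, 0.32 between 22Rv1 and LNCaP95, and -0.02 between LNCaP and LNCaP95, where genes are not independent replicates.

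**Figure D3:**
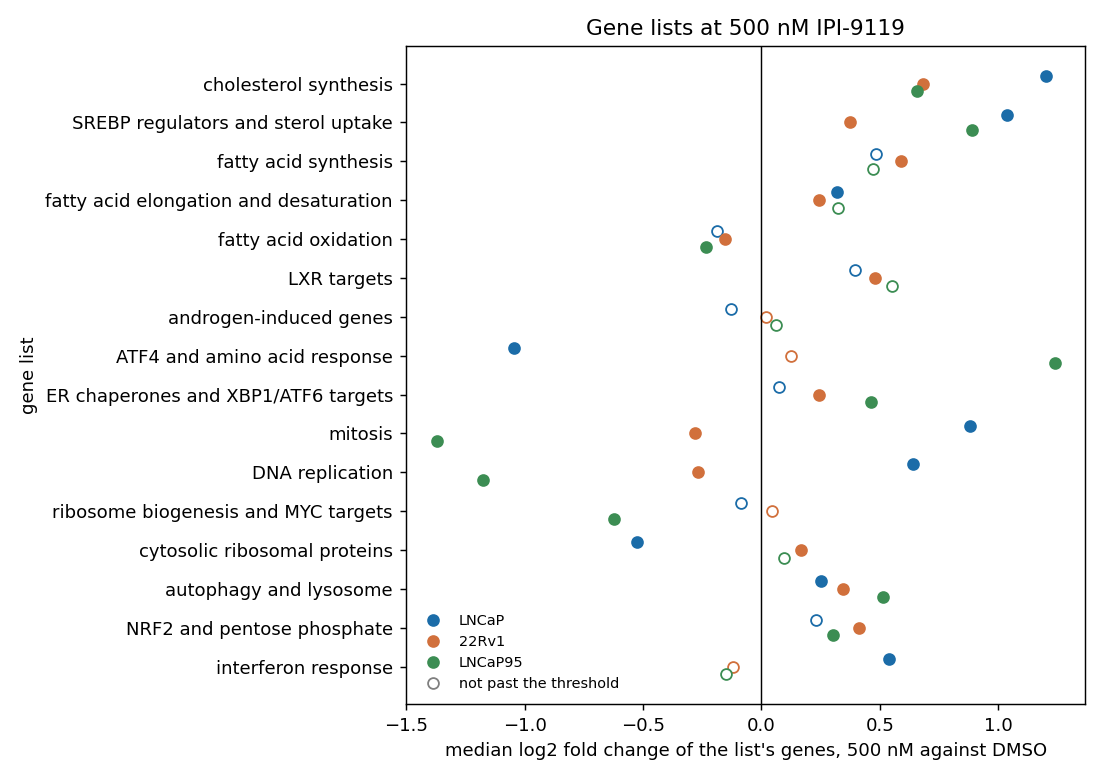
Median log2 fold change at 500 nM against DMSO (horizontal axis) over the measured genes of 16 lists (vertical axis), with a point for each cell line, filled where camera's adjusted p at the preset correlation passed the threshold and open where it did not. Cholesterol synthesis lay at 1.20 in LNCaP, 0.68 in 22Rv1 and 0.66 in LNCaP95, while the ATF4 list lay at -1.05 in LNCaP and 1.24 in LNCaP95.

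Differences of the 500 nM effect between lines, tested as contrasts over all 27 libraries, asked whether the response differs by line. Between LNCaP95 and LNCaP, stress genes differed. The effect in LNCaP95 exceeded that in LNCaP by 2.13 ± 0.182 for ATF4 (adjusted p = 6.3e-09), 2.69 ± 0.214 for ASNS, 2.89 ± 0.244 for TRIB3 and 3.43 ± 0.215 for PCK2 on the log2 scale. Over the ATF4 list, 31 of 32 genes had the more positive effect in LNCaP95 (median 2.16, adjusted p = 1.48e-29, adjusted p = 0.0716 with an estimated correlation). The reverse held for all 26 mitosis genes (median -2.26, adjusted p = 5.08e-15, adjusted p = 0.517 with an estimated correlation) and all 31 DNA replication genes (median -1.84, adjusted p = 9.48e-23, adjusted p = 0.331 with an estimated correlation), CDK1 at -3.53 ± 0.347 for example. KLK3 (2.56 ± 0.255) and TMPRSS2 (1.30 ± 0.268) had the more positive effect in LNCaP95. Ribosome biogenesis genes (14 lower and 1 higher of 23, 15 and 1 adjusted over the list alone, median -0.49, adjusted p = 4.6e-05, adjusted p = 0.517 with an estimated correlation) and ribosomal protein genes (18 higher of 25, 21 adjusted over the list alone, median 0.60, adjusted p = 1.33e-05, adjusted p = 0.645 with an estimated correlation) differed as well. FASN was at -1.16 ± 0.519 (adjusted p = 0.0788) and SCD at -0.99 ± 0.528 (adjusted p = 0.141), and with the replicate block both passed (0.00227 and 0.0114). SREBF1 (0.08 ± 0.219, adjusted p = 0.814) and CPT1A (-0.43 ± 0.264, adjusted p = 0.207) did not pass. Cholesterol synthesis genes had 1 more positive and 6 more negative of 20, 2 and 7 adjusted over the list alone (median -0.42, adjusted p = 0.0527). With the block that list passed (0.00478, adjusted p = 0.551 with an estimated correlation), while fry gave 0.156 for a common direction and 0.00391 for change in either direction. In this comparison 4571 of 11761 genes differed, 2327 more positive in LNCaP95 and 2244 more negative (50.9% positive, 39.5% at equal totals).

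Between 22Rv1 and LNCaP, 1683 genes differed, 798 more positive in 22Rv1 and 885 more negative (47.4% positive, 21.4% at equal totals). ASNS differed by 1.78 ± 0.214 (adjusted p = 2.8e-06), ATF4 by 1.02 ± 0.182, KLK3 by 1.43 ± 0.255 and CDK1 by -2.07 ± 0.347. The ATF4 list had 26 genes more positive and 1 more negative of 32, 26 and 2 adjusted over the list alone (median 1.14, adjusted p = 1.49e-22, adjusted p = 0.193 with an estimated correlation). Mitosis had 9 more negative of 26, 25 adjusted over the list alone (median -1.11, adjusted p = 1.58e-10, adjusted p = 0.451 with an estimated correlation). Ribosomal proteins had 20 more positive of 25, 24 adjusted over the list alone (median 0.71, adjusted p = 3.98e-14, adjusted p = 0.314 with an estimated correlation). FASN (-0.46 ± 0.519, adjusted p = 0.618) and SCD (-0.53 ± 0.528, adjusted p = 0.569) did not pass. Between LNCaP95 and 22Rv1, 2983 genes differed, 1527 more positive in LNCaP95 and 1456 more negative (51.2% positive, 61.6% at equal totals). DDIT3 differed by 2.53 ± 0.272 (adjusted p = 1.46e-06), ATF4 by 1.11 ± 0.182, CPT1A by -1.09 ± 0.264 and CCND1 by -1.32 ± 0.183. The ATF4 list had 27 of 32 more positive, 29 adjusted over the list alone (median 1.07, adjusted p = 2.1e-17, adjusted p = 0.218 with an estimated correlation). DNA replication had 28 of 31 more negative, 30 adjusted over the list alone (median -0.91, adjusted p = 2.61e-13, adjusted p = 0.544 with an estimated correlation). Ribosome biogenesis had 19 of 23 more negative, with 1 more positive and 21 more negative adjusted over the list alone (median -0.67, adjusted p = 6.47e-12, adjusted p = 0.117 with an estimated correlation).

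The DMSO libraries of the castration-resistant lines were compared with those of LNCaP to ask how the lines differ without the inhibitor (n = 3 libraries per group). Each line had its own letter in the sample titles (A, B or C). Line, androgen status and any handling by letter cannot be told apart here. In 22Rv1, androgen-regulated genes stood at 562 ± 65.5 normalised counts for KLK3 against 12450 ± 648 in LNCaP (SD, log2 difference -4.47 ± 0.181, adjusted p = 1.07e-16) and 820 against 10670 for TMPRSS2 (-3.69 ± 0.19). FKBP5 was higher at 11080 against 844 (3.76 ± 0.154) and CCND1 at 23050 against 2637 (3.14 ± 0.13). Androgen-induced genes had 11 higher and 21 lower of 37 (median -0.66, adjusted p = 0.0775, and 2.62e-05 under fry). Mitosis genes were higher in 26 of 26 cases (median 2.34, adjusted p = 3.55e-06, adjusted p = 0.818 with an estimated correlation) and DNA replication genes in 30 of 31, with 1 lower (median 2.18, adjusted p = 1.64e-09, adjusted p = 0.818 with an estimated correlation). Cholesterol synthesis genes had 15 higher and 3 lower of 20 (median 1.57, adjusted p = 0.0174, adjusted p = 0.818 with an estimated correlation), HMGCS1 at 2.54 ± 0.291. All 11 immediate early genes were higher (median 1.69, adjusted p = 0.00528, adjusted p = 0.736 with an estimated correlation). Neuroendocrine markers had 8 higher and 1 lower of 10 (median 5.37, adjusted p = 0.00698, adjusted p = 0.172 with an estimated correlation), with the granins and granin-like genes CHGB at 8.68 ± 0.37 and SCG3 at 10.03 ± 0.423 (1653 counts against 0.649). ALB stood at 14190 counts against 1.09, and SPON2 at 16.3 against 39010. The calls for the ATF4 list (6 higher and 23 lower of 34, median -0.57, adjusted p = 0.0161, adjusted p = 0.818 with an estimated correlation), ribosomal proteins (1 higher and 17 lower of 25, median -0.57, adjusted p = 0.0125, adjusted p = 0.818 with an estimated correlation) and p53 targets (5 higher and 14 lower of 21, 15 lower adjusted over the list alone, median -0.92, adjusted p = 0.0449, adjusted p = 0.736 with an estimated correlation) were lost under quantile normalisation (0.145, 0.424 and 0.139).

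Untreated LNCaP95 differed from untreated LNCaP in 9325 of 14026 genes, and 22Rv1 in 10489. The share higher in LNCaP95 was 51.1%, and 63.3% at equal totals, a scaling that moved the median of all genes from 0.007 to 0.214 in this comparison. KLK3 stood at 835 counts against 12450 (log2 difference -3.90 ± 0.181), TMPRSS2 at 355 against 10670 (-4.92 ± 0.19) and KLK2 at -3.49 ± 0.221, while FKBP5 was higher by 1.36 ± 0.154. Androgen-induced genes had 8 higher and 22 lower of 37 (median -0.97, adjusted p = 0.00213, adjusted p = 0.583 with an estimated correlation). Ribosomal protein genes were lower in 25 of 25 cases (median -2.03, adjusted p = 5.52e-15, adjusted p = 0.583 with an estimated correlation), RPL3 at 19870 counts against 123700 (-2.64 ± 0.131) and RPS6 at -2.56 ± 0.131. CDK1 was higher by 3.45 ± 0.247, with 26 of 26 mitosis genes (median 2.25, adjusted p = 4.37e-08, adjusted p = 0.583 with an estimated correlation) and 30 of 31 DNA replication genes (median 1.55, adjusted p = 1.04e-10, adjusted p = 0.583 with an estimated correlation). The ATF4 list had 1 higher and 27 lower of 34, 28 lower adjusted over the list alone (median -0.83, adjusted p = 3.84e-06, adjusted p = 0.583 with an estimated correlation), ATF4 at -1.15 ± 0.129, ASNS at -1.72 ± 0.152 and TRIB3 at -2.21 ± 0.174. ER chaperones had 16 higher and 2 lower of 25 (median 0.66, adjusted p = 0.00213, adjusted p = 0.583 with an estimated correlation). Fatty acid oxidation genes had 1 higher and 10 lower of 21 (median -0.37, adjusted p = 0.0356, adjusted p = 0.583 with an estimated correlation), a call lost at equal totals (adjusted p = 0.105). PREX1 stood at 1930 counts against 0.316 in LNCaP, and NCAM2 at 5.29 against 15530.

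**Figure D4:**
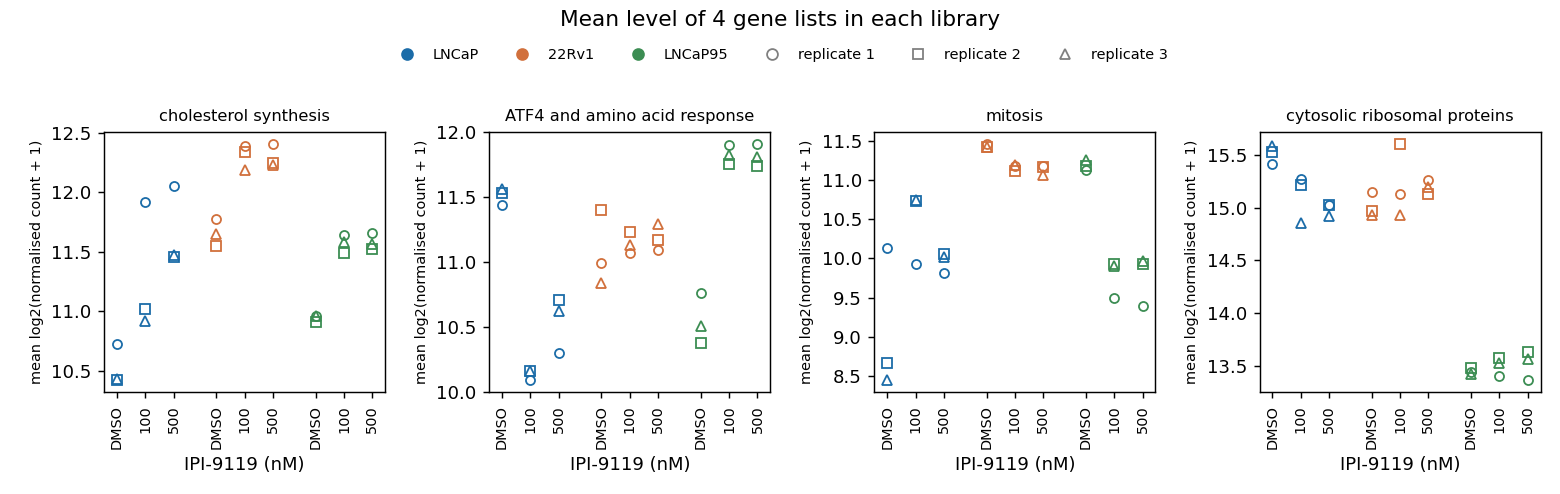
Mean log2(normalised count + 1) over the genes of 4 lists (vertical axis) in each library, by cell line (colour), IPI-9119 concentration (horizontal axis) and replicate (symbol). The mitosis list in LNCaP lay at 10.13, 8.66 and 8.44 with DMSO and at 9.81, 10.06 and 10.02 at 500 nM.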

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

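Chosen after the result was seen were the tests on exchanged labels, on single libraries and on growth conditions for the amino acid response genes.

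These results stood out because the 500 nM effect differed between cell lines in a test of the difference itself. Between 22Rv1 and LNCaP, 1683 genes differed, CDK1 by -2.07, with list medians of -1.11 for mitosis, -0.90 for DNA replication, -0.75 for androgen synthesis and 0.71 for cytosolic ribosomal proteins. These lists had an adjusted p of 0.451, 0.314, 0.314 and 0.314 with an estimated correlation, against 1.58e-10, 3.93e-16, 0.0014 and 3.98e-14 at the preset one. Of 100 splits of treated and DMSO libraries, 2 gave as many genes, the real one included, with 2845 as the highest of the others. Such splits can keep the effect of a single line, so for these differences they settle nothing about chance.

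Between LNCaP95 and LNCaP, 4571 genes differed. The cholesterol exporter ABCA1 differed by -1.86, KLK3 by 2.56, ATF4 by 2.13, ASNS by 2.69, TRIB3 by 2.89, XBP1 by 1.27 and CDK1 by -3.53. List medians were 2.16 for the ATF4 response, -2.26 for mitosis and -1.84 for DNA replication (adjusted p = 0.0716, 0.517 and 0.331 with an estimated correlation). Of 100 splits, 1 gave as many genes, the real one, with 3816 as the highest of the others, which leaves chance open for the reason given above.

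Between LNCaP95 and 22Rv1, 2983 genes differed, ABCA1 by -2.47 and KLK3 by 1.13, with list medians of -0.65 for glycolysis and -0.60 for heat shock. These lists had an adjusted p of 2.47e-05 and 1.22e-06 at the preset correlation, and of 0.667 and 0.221 with an estimated correlation. Of 100 splits, 7 gave as many genes, with 3503 as the highest of the others, which again decides nothing.

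The ATF4 and amino acid response genes were lower in treated LNCaP and higher in treated LNCaP95. The cholesterol synthesis list rose in LNCaP with a median of 1.2, which argues against an exchange of treated and DMSO labels there. This presumes that the inhibitor raises these genes in LNCaP as in the other lines. The list did not pass with an estimated correlation. A single aberrant LNCaP library was excluded as the cause, since the list's median stayed at or below -0.89 with any 1 of the 6 libraries left out. Scaling between libraries was excluded too, since the difference had a median of at least 2.06 under quantile normalisation and at equal totals. What stays open is poorer growth of the LNCaP cultures during the 6 days with DMSO, which could have raised these genes there alone. A rise before treatment would be shared by the treated cultures and could not give this difference. The list was lower in untreated LNCaP95 than in untreated LNCaP (median -0.83), and the mitosis list was higher (median 2.25). These values go with poorer growth, but other differences between the lines could give them too. In LNCaP DMSO replicate 1 the mitosis level lay above those of the other DMSO libraries and of the higher dose. With LNCaP replicates 2 and 3 only, the mitosis medians against DMSO were 1.46 at 500 nM and 2.23 at 100 nM, both larger than with all replicates. The ATF4 list's medians were then -0.89 and -1.295, a fall that was smaller at 500 nM and nearly the same at 100 nM. This rests on leaving out 1 replicate number, so it does not decide about growth. The androgen dependence of the lines, which the labels name, was not tested apart from growth.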

How the results depend on the processing

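Added after the data were seen were the fits of LNCaP replicates 2 and 3 only, fry, equal totals for lists, and lists without 22Rv1 DMSO replicate 3.

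Array weights moved the number of genes changed to 5781 in LNCaP at 100 nM, 6030 at 500 nM and 123 between doses, to 307 and 3729 in 22Rv1, and to 3900 (22Rv1 against LNCaP) and 4792 (LNCaP95 against 22Rv1) for differences of effect. With only the 6 libraries compared, counts were 2158 (LNCaP 100 nM), 0 (LNCaP doses), 355 (22Rv1 100 nM) and 1433 (22Rv1 500 nM). The count between LNCaP doses was 0 with the replicate block, 93 with DESeq2, 49 with all 27 libraries in 1 fit and 755 with LNCaP replicates 2 and 3 only. The cause was not tested.

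Leaving out 1 library gave 1736 to 4617 genes for LNCaP at 100 nM, 1475 to 3891 at 500 nM and 0 to 67 between doses. It gave 261 to 1184 and 384 to 697 for 22Rv1, 5622 to 6167 and 5869 to 6189 for LNCaP95, and 0 to 0 between doses in both. It gave 2122 to 2673 for the common effect. Differences of effect ranged over 1250 to 2196 (22Rv1 against LNCaP), 3949 to 4975 (LNCaP95 against LNCaP) and 2284 to 2856 (LNCaP95 against 22Rv1), and untreated lines over 9250 to 10185 and 8589 to 9083.

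With an estimated correlation, camera called 0 lists in every comparison. fry called 9 lists for LNCaP at 100 nM, 0 between LNCaP doses, 0 between 22Rv1 doses, 25 and 24 for LNCaP95, and 21 and 17 for untreated 22Rv1 and LNCaP95. With LNCaP replicates 2 and 3 only, 19 lists were called at 500 nM.

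Quantile normalisation reversed CD68 (-1.275) in untreated 22Rv1, MT-CO3 (0.57) and HSP90AA1 (0.16) in untreated LNCaP95, and the ribosomal protein list in 22Rv1 at 100 nM (-0.025) and 500 nM (-0.012). For phospholipid synthesis in LNCaP95 at 100 nM (median 0.026 in both), camera put the direction down (adjusted p = 0.999) and fry up (0.049). The cause was not tested. Of named gene results, 2263 stayed on their side of the threshold under quantile normalisation and 39 were lost, 2308 and 23 with edgeR, 2234 and 30 with the block, 2281 and 70 with no filter, 2128 and 48 with array weights (175 gained), 1267 and 86 with all 27 libraries in 1 fit, 1312 and 55 with only the 6 libraries compared, and 17485 and 898 over single libraries left out.

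Every same-numbered pair of libraries correlated at over 0.1 in LNCaP95 and in the LNCaP comparisons with 500 nM. This did not hold between LNCaP DMSO and 100 nM or in 22Rv1. Between 22Rv1 DMSO and 100 nM, pairs of different numbers ranged from -0.53 to 0.52, past the highest same-numbered pair there (0.39). Differences shared across those groups are therefore not taken up by the block. For LNCaP DMSO and 500 nM, pairs of different numbers reached 0.13, the lowest value of same-numbered pairs. With the block, lists called went from 12 to 14 in LNCaP at 500 nM, from 13 to 15 between LNCaP doses, and in LNCaP95 from 14 to 17 at 100 nM and from 13 to 15 at 500 nM.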

Other observations

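Chosen after the result was seen were all 3 tests on 22Rv1 DMSO replicate 3.

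Some gene groups not described above passed as lists at 500 nM. In LNCaP at 500 nM, mitochondrially encoded genes had 0 called of 13 but passed as a list (median 0.45, adjusted p = 0.0352, adjusted p = 0.681 with an estimated correlation, 0.327 under fry), a call also lost with the replicate block (0.0643). With LNCaP replicates 2 and 3 only, that list had a median of 0.96 (adjusted p = 1.19e-06). Autophagy and lysosome genes had 7 up of 18, 8 up and 1 down adjusted over the list alone (median 0.25, adjusted p = 0.014, adjusted p = 0.522 with an estimated correlation). In 22Rv1 at 500 nM, elongation and desaturation genes had 4 up of 15, 7 up and 1 down adjusted over the list alone (median 0.24, adjusted p = 0.000349, adjusted p = 0.181 with an estimated correlation). Glycolysis genes had 3 up of 20, 4 adjusted over the list alone (median 0.20, adjusted p = 0.000426, adjusted p = 0.369 with an estimated correlation, 0.0593 under quantile normalisation, 0.0767 under fry). ER chaperones had 3 up of 25 (median 0.24, adjusted p = 0.000101, adjusted p = 0.287 with an estimated correlation, 0.0767 under fry), and heat shock genes 2 up of 12, 3 adjusted over the list alone (median 0.24, adjusted p = 0.000963, adjusted p = 0.315 with an estimated correlation, 0.0769 under fry), a call also lost under quantile normalisation. Androgen-repressed genes had 3 down of 6 (median -0.33, adjusted p = 0.00697, adjusted p = 0.219 with an estimated correlation), and androgen synthesis genes 2 down of 8 (median -0.15, adjusted p = 0.0437, adjusted p = 0.4 with an estimated correlation, 0.0576 under fry), a call also lost under quantile normalisation. Ribosomal proteins had 0 called of 25 (median 0.17, adjusted p = 0.00257, adjusted p = 0.662 with an estimated correlation, 0.432 under fry, 0.5 in the other direction under quantile normalisation).

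Other lists did not pass at 500 nM with camera, which sets a list against the other genes. Triglyceride and droplet genes had an adjusted p of 0.341 in LNCaP, 0.987 in 22Rv1 and 0.507 in LNCaP95, and fatty acid uptake genes of 0.102, 0.407 and 0.709. With the replicate block, fatty acid uptake passed in LNCaP (0.0408, adjusted p = 0.476 with an estimated correlation; 0.0237 with replicates 2 and 3 only), as did androgen-repressed genes in LNCaP95 (0.0469 against 0.11 without it, adjusted p = 0.203 with an estimated correlation). At 100 nM in LNCaP95 the block added fatty acid synthesis (0.0372), androgen-repressed (0.0456) and mitochondrially encoded genes (0.0201), with adjusted p = 0.201, 0.201 and 0.611 with an estimated correlation. Hypoxia genes had 0.325, 0.63 and 0.219, with 6 up and 3 down of 13 in LNCaP (median -0.07, mean 0.22), and p53 targets 0.942, 0.152 and 0.262, with 10 up and 6 down of 21 in LNCaP95. Luminal markers had 0.424, 0.62 and 0.652, and fibroblast markers 0.0847, 0.522 and 0.885, with 3 up of 7 in LNCaP, among them COL3A1 at 2.94 ± 0.215 and VIM at 1.69 ± 0.284. Basal markers were too few to test, with 1 up and 2 down of 4 in LNCaP, as were leukocyte markers, with CD68 up by 1.92 ± 0.29 in LNCaP. Neuroendocrine markers had 0.522 in 22Rv1 and 0.913 in LNCaP95. Under fry some of these lists passed: fatty acid uptake in 22Rv1 (0.031) and LNCaP95 (0.00239), p53 targets in 22Rv1 (0.0224) and LNCaP95 (0.000363), fibroblast markers in LNCaP (0.0168), and in LNCaP95 also triglyceride and droplet genes (0.000857), hypoxia genes (0.0436) and luminal markers (0.00855). In untreated LNCaP95, interferon response genes had 9 higher and 4 lower of 17 (median 1.01, adjusted p = 0.132, and 3.23e-08 under fry), with BST2 at 5.89 ± 0.309.

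Cytosolic ribosomal protein genes were lower in untreated LNCaP95 than in untreated LNCaP, 25 of 25. A loss of short transcripts stays open: genes matched for level and length had a median of -0.01, but the longest annotated transcripts used as lengths ran from 1047 to 5396 nt, past the median of 3660 nt over the tested genes. Scaling between libraries was excluded, since the list's median was at or below -1.54 under quantile normalisation and at equal totals. Other mRNAs with a 5' terminal oligopyrimidine tract, which are regulated together with ribosomal proteins, had a median of -1.67. A shared regulation of mRNA levels in that class would give this, a hypothesis found and tested on the same data. These mRNAs were not matched for length or level, so the value does not separate it from a loss of short transcripts.

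In 22Rv1 DMSO replicate 3, 1528 of 2007 genes silent in the other 8 libraries held 3549 reads, with at most 16 per gene. Deeper sequencing was excluded, since the library had 19.1 M reads (19061854), within the range of the others. RNA of another cell type and DNA in the library could not be told apart. The top 1% of these genes held 7.2% of the reads, but counts this low decide nothing, and DNA was tested with a rho of 0.29 between reads and transcript length over 1788 genes, which are not independent replicates. No biological explanation was tested.

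For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In LNCaP the real counts were 3250, 2671 and 1 (100 nM, 500 nM and between doses), each given by 1 of 10 splits, with 0 as the highest of the others. In 22Rv1 the counts were 889, 946 and 0. At 100 nM, 2 of 10 splits gave as many, the other with 1223 genes, which set DMSO replicate 1 with 100 nM replicates 1 and 2. The deviations of DMSO replicate 1 and 100 nM replicate 2 from their group means correlated at 0.52. At 500 nM 1 of 10 did, with 0 as the highest other, and between doses 10 of 10. In LNCaP95 the counts were 6713, 6715 and 0, given by 1, 1 and 10 of 10 splits, with 0 as the highest other each time. Untreated 22Rv1 and LNCaP95 had 10489 and 9325, each given by 1 of 10, with 0 and 3 as the highest other. For the common effect, 1 of 100 splits gave as many as the real 2658, the real one, with 1358 as the highest other. That argues against no effect in any line, but the effect of a single line could give such a count. The splits also ignored the replicate numbers, and replicates may be technical, so chance between cultures stays open.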
